A study of Rattus norvegicus with 97 samples.

How the data were processed

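RNA from the nucleus accumbens shell, a ventral part of the striatum that takes part in reward, was measured on 97 Affymetrix rat 3' expression arrays, 1 array per animal. The animals came from 5 pairs of rat lines that had been bred for high or for low alcohol consumption: P and NP, HAD1 and LAD1, HAD2 and LAD2, AA and ANA, and sP and sNP. Each line had 10 animals except LAD1, sP and sNP with 9 each. Line and animal number were read from the labels, which give neither the sex nor the alcohol exposure of the animals. Per the labels' protocols, RNA was extracted with Trizol and cleaned on RNeasy columns, and 25 ng of total RNA went through 2 cycles of amplification before biotin labelling. Per the submitters' processing notes, the signals were summarised with RMA, whose version is not given in the sources used here. The deposited values are log2 RMA signals, and they were used as deposited, with no further scaling. They ran from 3.56 to 16.06 over 31099 probe sets, and the array medians lay between 7.82 and 8.02. Raw intensity files were not used here. The number of arrays per line limits the precision of each difference.

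Of the 31099 probe sets, 57 AFFX controls were left out of the tests, which leaves 31042. Of these, 20826 carried 1 gene symbol, 436 carried several and 9780 carried none, so that 14217 genes had a symbol and 4525 of them had 2 or more probe sets. Counts cover all 31042 probe sets, whereas names are given only to probe sets with 1 symbol. No genome build is named in the sources used here, so no positions are given, and a table of current rat genes served only for names and for the order of neighbours.

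Groups, tests, fixed gene lists, the rule for named genes and most alternatives were chosen before the data were examined. In each line pair the preferring line was compared with the non-preferring line in a fit of its own with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, two-sided). Differences are preferring minus non-preferring on the log2 scale, and each is followed by its standard error where one is given. P-values were adjusted by the method of Benjamini and Hochberg over the 31042 probe sets, and a probe set was called at an adjusted p under 0.05. A limma fit with 1 mean per line gave the unweighted average of the 5 differences, with the spread between animals as its error, and an F test of whether the 5 differences were equal (the interaction). A separate limma fit took the 5 differences of line means as the replicates, since the line is the unit that was bred. The overlap of the 5 lists of calls was set against the number expected for independent lists with the same counts of higher and lower calls. Correlations of the differences between line pairs run across probe sets, which are not independent replicates, and were set against 100 permutations of preference within line pairs. No pairing of animals was assumed: animal numbers are shared between lines only in P/NP and sP/sNP, and the labels do not call these numbers pairs.

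Gene groups were tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene (the brightest with 1 symbol), and again with an estimated correlation. There were 31 fixed pathway lists and 16 fixed lists of cell type markers, adjusted separately within each comparison; of their 866 genes 775 were measured. Members of a list were also adjusted over the list alone.

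The rule for named genes was as follows. For each pair it took the 12 largest positive and 12 largest negative differences among called probe sets whose lowest animal in 1 line lay above the highest animal in the other. For the average it took the 12 largest in each direction among calls with the same sign in all 5 pairs, together with any gene called the same way in at least 4 pairs. For the lists it took up to 4 members with the smallest adjusted p. Provisional symbols were skipped, and the skipping of symbols with the Rik suffix was added after such a symbol was seen.

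Each array received a label score, computed from the 50 probe sets that best parted the lines of its pair in the other animals, which is 0 at the non-preferring median and 1 at the preferring median, with the median taken over these probe sets. The arrays further than 0.3 from the end named on their label are called departing arrays, and there were 8. This limit was set after the data were seen. No array was relabelled or moved. All counts are given with all 97 arrays, and those that lead a comparison also without the departing arrays. Since the score itself uses the line difference, a higher count without these arrays is not independent evidence of more differences. A marker index per array, the mean of the spiny neuron markers minus the mean of the markers of ventral pallidum, septum and basal forebrain, was compared between the lines of each pair, as was the difference between the Affymetrix Gapdh 3' and 5' probe sets, a measure of RNA integrity and labelling. These 10 tests form a family of permutation tests with scipy 1.17.1 and numpy 2.4.6, two-sided, exact where a line had fewer than 10 animals and with 100000 resamples elsewhere. Figures were drawn with matplotlib 3.10.9.

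Alternatives chosen before the data were examined were a fit over all 10 lines, the animal number as a replicate block in P/NP and sP/sNP, leaving out the dimmest 40% of probe sets or those with a mean log2 value under 6, subtraction of array medians, quantile normalization, trended and robust eBayes, array weights, the Gapdh value as covariate, a minimum fold of 1.1 (treat), 1 probe set per gene, leaving out each line pair, and the mean of a gene's probe sets for the lists. Alternatives added after the data were seen were leaving out the departing arrays, leaving out each array in turn, the marker index as covariate, and the index together with the departing arrays left out. For each result 100 splits of the animals within line pairs (seed 1, the real split included) were counted as well.

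The pipeline was tested on simulated data with 200 changed probe sets on noise with the means and standard deviations of the real arrays. The noise was drawn independently for each probe set, without the correlation between probe sets of real arrays, so recovery there may differ. Folds of 1.2 and 1.5 were each given to 67 of the 200. At a fold of 1.5 the fits recovered 88.1% of them in P/NP, 94% in HAD1/LAD1, 92.5% in HAD2/LAD2, 94% in AA/ANA and 92.5% in sP/sNP; at a fold of 1.2 they recovered 26.9%, 52.2%, 41.8%, 35.8% and 38.8%. The fit with the line pair as replicate recovered 82.1% at a fold of 1.2, but the simulation gave the same difference to all 5 pairs with no spread between pairs, so this does not describe its power on differences that vary between pairs.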

Results

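Gene expression in the nucleus accumbens shell was measured on 97 arrays, 1 per rat, from 5 pairs of rat lines. In each pair 1 line had been bred to prefer and consume alcohol (P, HAD1, HAD2, AA and sP) and the other to avoid it (NP, LAD1, LAD2, ANA and sNP). There were 10 animals of each line except LAD1, sP and sNP, with 9 each. The deposited log2 RMA values of 31042 probe sets were compared between the lines of each pair, on average over the pairs, and between pairs. Array medians lay between 7.82 and 8.02, and none of the 57 Affymetrix control probe sets was called in any pair with limma (lowest adjusted p 0.307, in HAD1/LAD1). The comparisons address which genes of this region differ between lines bred for different alcohol intake, and which of these differ the same way in several pairs.

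Most animals lay close to their own line on the genes that part the lines of their pair, but 8 arrays did not. The label score is 0 at the median of the non-preferring line and 1 at the median of the preferring line. The array labelled HAD1 28 had a score of 0.00493 and LAD1 37 one of 0.988. AA 19 had -0.039 and ANA 20 had 0.93; P 9 had 0.463 and NP 9 had 1.05. The arrays labelled sP 4 and sNP 4 had 0.399 and 0.483. All arrays kept their labels, and counts of called probe sets are given with all arrays and without these 8 departing arrays, a choice made after the data were seen.

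**Figure D1:**
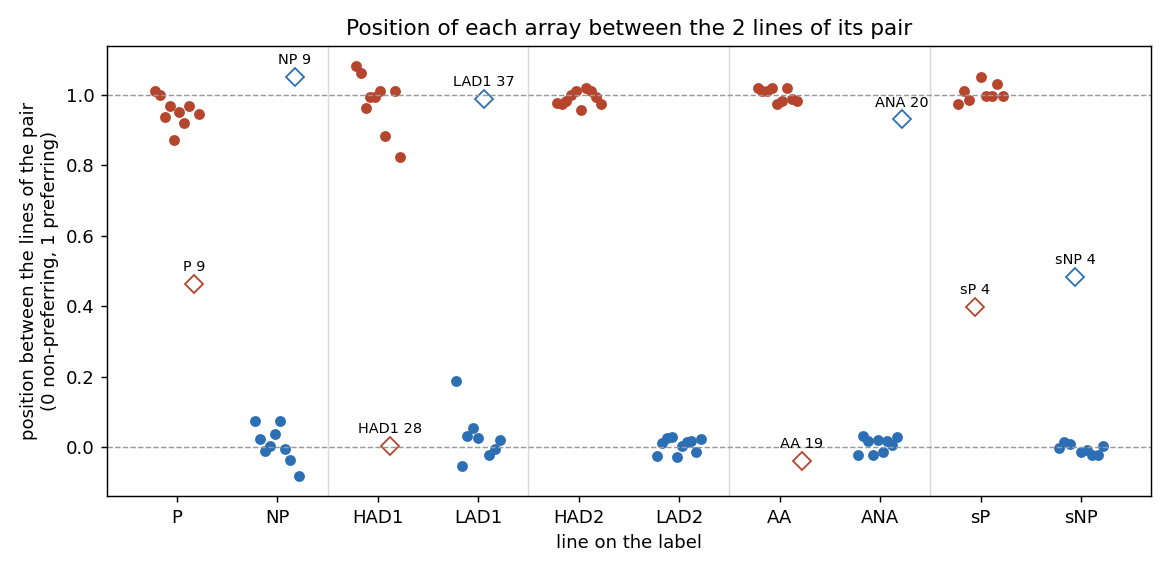
Label score of each array (vertical axis, no unit; 0 is the median of the non-preferring line and 1 that of the preferring line of the pair) by the line on its label, with 1 mark per array. The 8 departing arrays are named open diamonds, such as HAD1 28 at 0.00493 and LAD1 37 at 0.988.

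In P rats against NP rats, Spint1, an inhibitor of cell surface serine proteases, was 1.9-fold higher (0.93 ± 0.141 log2, adjusted p = 0.00197). Prohibitin 2 (Phb2), a protein of the inner mitochondrial membrane, was lower (-0.81 ± 0.133, adjusted p = 0.00312; 1 of its probe sets). Also lower were the acetyltransferase family member Nat8f3 (-0.70 ± 0.135, adjusted p = 0.0093), the spliceosomal cyclophilin Ppih (-0.37, adjusted p = 0.0186; 1 of 2 probe sets) and the zinc finger genes Zfp715 (-0.35, adjusted p = 0.00442) and Zfp455 (-0.28, adjusted p = 0.00692). Tmem205 (0.17, adjusted p = 0.0303) and Sdf4, a calcium-binding protein of the Golgi (0.15, adjusted p = 0.0443), were higher in P. For each of these genes every array labelled P lay on 1 side of every array labelled NP. This includes NP 9, at the P end of the label score (1.05), and P 9 (0.463). With all arrays the rule therefore passes over genes that follow that score closely. Gsta4, a glutathione transferase that detoxifies products of lipid peroxidation, was higher in P (0.75 ± 0.153, adjusted p = 0.0145). Uqcrfs1, a subunit of respiratory complex III, was higher too (0.34, adjusted p = 0.0192), and the immunoproteasome subunit Psmb8 was lower (-0.45, adjusted p = 0.025).

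Without the arrays labelled P 9 and NP 9, 9 animals against 9, the named genes of this pair had larger differences. Sik1, a kinase that restrains CREB-dependent transcription, was 6.85-fold higher in P (2.78 ± 0.145, adjusted p = 4.72e-10). The myeloid receptor Siglec5 was 5.33-fold higher and the chemokine Ccl6 3.88-fold. The DNA ligase Lig4 (0.90, both of its probe sets) and the nuclear body protein Sp110 (0.92, 3 of 3 probe sets) were higher as well. The actin-bundling protein Pls1 (-1.56), the mitotic kinesin Kif15 (-1.19), the riboflavin transporter Slc52a2 (-1.17, 1 of 2 probe sets), the lectin receptor Clec4a3 (-1.13) and the Fc receptor-like gene Fcrl2 (-1.13) were lower in P.

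Microglial markers were lower in P as a group (camera adjusted p = 1.56e-10; adjusted p = 0.3 with an estimated correlation). Of 12 measured, only Laptm5 was called (-0.33, adjusted p = 0.0491), and 8 were lower when adjusted over the list alone. Tmem119 (-0.38), Aif1 (-0.36) and Ctss (-0.29) did not pass over all probe sets. Proteasome genes were called higher as a list with none of 30 members called (adjusted p = 0.00471; adjusted p = 0.991 with an estimated correlation). Markers of blood cells (adjusted p = 0.00526), endothelial cells (0.0273) and cholinergic interneurons (0.0455) were also called higher as lists, each with an adjusted p = 0.395 with an estimated correlation. They had 0 called members, and 0, 2 and 0 adjusted over the list alone. Without P 9 and NP 9 the proteasome (adjusted p = 0.0706), endothelial (0.07) and cholinergic (0.121) lists were no longer called. In total 326 probe sets (1.05%) were called, 188 higher and 138 lower in P, and 180 with the Gapdh value as covariate. Of these 13 did not overlap between the lines (chance gives 0.0011% of probe sets). Without P 9 and NP 9 the count was 661, with 318 of the 326 among them, and 203 did not overlap. Leaving out NP 9 alone gave 552.

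In HAD1 rats against LAD1 rats, Gpnmb, a glycoprotein of phagocytic cells, was 1.41-fold lower (-0.50 ± 0.066, adjusted p = 0.00211) and Trappc12, which takes part in vesicle tethering, was higher (0.17 ± 0.037, adjusted p = 0.0299). The arrays labelled HAD1 and LAD1 did not overlap for either gene, HAD1 28 and LAD1 37 included. These 2 arrays lie at the end of the other line on the label score (0.00493 and 0.988). With all arrays the rule therefore passes over genes that follow that score. Among members of the fixed lists, the growth factor Nrg1 was 2.54-fold higher (adjusted p = 0.00835) and the synaptic kinase anchor Akap5 was lower (-1.10, adjusted p = 0.0117). The metabotropic glutamate receptors Grm5 (-1.12, adjusted p = 0.0168) and Grm2 (-0.45, adjusted p = 0.0346) and the peptide Nmb (-1.82, adjusted p = 0.0191) were lower in HAD1. The transporter Abcb1a (-0.41, adjusted p = 0.0184) and Gsta4 (-0.86) were lower, and the endothelial receptor Tek (0.43, adjusted p = 0.03) was higher.

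Without the arrays labelled HAD1 28 and LAD1 37, 9 animals against 8, the largest differences among the named genes were in Mis18a, a protein needed for centromere assembly, and the interferon-induced GTPase Mx2. Mis18a was 14.3-fold lower in HAD1 (-3.84 ± 0.128, adjusted p = 1.44e-13) and Mx2 12.1-fold lower (-3.60 ± 0.093, adjusted p = 1.75e-15; both of its probe sets). The endosomal GTPase Rab22a (-1.98), the receptor phosphatase Ptprj (-1.94), the interferon lambda receptor Ifnlr1 (-1.58), Akap5 (-1.35), the actin-severing protein Gsn (-1.24) and the kinase Rock2 (-1.17) were lower. Plekhh1 (7.8-fold), the amylase gene Amy1 (6.61-fold), Kif15 (4.49-fold), Ints13 (4.39-fold), the myosin Myo5c (4.17-fold), the sorting nexin Snx10 (3.76-fold, both probe sets), Nrg1 (3.04-fold) and cyclin Ccnd2 (2.9-fold) were higher. Of the probe sets of these genes only 1 of 2 had the sign given for Plekhh1 and Ptprj, 1 of 3 for Ints13, 2 of 3 for Myo5c, 3 of 4 for Rock2 and 7 of 8 for Nrg1.

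Interferon response genes were higher in HAD1 as a list (adjusted p = 3.54e-05; adjusted p = 0.788 with an estimated correlation). Of 25 members Oas1b (1.04, adjusted p = 0.0151) and the transcription factor Irf7 (0.49, adjusted p = 0.0477) were called, and 6 higher and 1 lower adjusted over the list alone. Oxidative phosphorylation genes were called lower as a list with none of 64 called (adjusted p = 0.00731; adjusted p = 0.984 with an estimated correlation, and 0.53 at the preset correlation without the departing arrays). Microglial markers were called lower as a list (adjusted p = 0.0136; adjusted p = 0.423 with an estimated correlation) with 0 of 12 called and 2 lower adjusted over the list alone. Markers of cholinergic interneurons were called lower (adjusted p = 0.0233; adjusted p = 0.458 with an estimated correlation) with 0 of 5 called and 1 lower adjusted over the list alone. In total 371 probe sets (1.2%) were called, 171 higher and 200 lower (145 in total with the marker index as covariate), 3 of them without overlap (chance 0.0022%). Without HAD1 28 and LAD1 37 the count was 1237, with 370 of the 371 among them, and 346 did not overlap. Leaving out HAD1 28 alone gave 754 and LAD1 37 alone 795. Other arrays whose omission moved the count by more than 1.5 times were HAD1 21 (216), HAD1 22 (231), HAD1 23 (246), HAD1 24 (228), HAD1 26 (239), HAD1 29 (231), LAD1 31 (243), LAD1 32 (178), LAD1 33 (224), LAD1 34 (187), LAD1 35 (208), LAD1 38 (226) and LAD1 40 (239).

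In HAD2 rats against LAD2 rats, Lysmd4 was 10.8-fold higher (3.43 ± 0.289, adjusted p = 3e-08) on 1 probe set, while its other 3 were lower (-0.74, -0.76 and -1.62). Mx2 was 10.6-fold higher (3.40 ± 0.136, adjusted p = 2.47e-13; 1 of its 2 probe sets), opposite to HAD1/LAD1. The class I MHC gene RT1-T24-4 (5.03-fold, adjusted p = 5.07e-13), Fcrl2 (4.43-fold), Kif15 (4-fold), the phosphatase Ctdspl (3.86-fold) and the anoctamin Ano5 (2.75-fold) were higher. So were the RNA methylation factor Wtap (2.61-fold), the coenzyme A synthesis kinase Pank3 (2.43-fold) and the interferon-induced Ifi27 (2.32-fold). The beta sarcoglycan Sgcb was 8.84-fold lower (-3.14 ± 0.174, adjusted p = 3.21e-11; 1 of 3 probe sets) and the metabotropic glutamate receptor Grm5 5.93-fold lower (-2.57 ± 0.189, adjusted p = 3.16e-09; both probe sets). The RNA-binding protein Elavl1 (-2.04), the amino acid transporter subunit Slc3a1 (-2.08), the dendritic Map2 (-1.93), the mitochondrial chaperone Hspa9 (-1.84), the mitochondrial transport adaptor Trak2 (-1.79), Slc52a2 (-1.69) and the membrane progestin receptor Paqr8 (-1.57) were lower. Every HAD2 animal lay on 1 side of every LAD2 animal for each of these. The sign given held for 1 of 2 probe sets of Map2, 2 of 3 of Elavl1, 3 of 4 of Hspa9 and of Pank3, and 3 of 5 of Ctdspl.

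Among listed genes in HAD2/LAD2, the NMDA receptor subunit Grin3a was higher (1.17, adjusted p = 6.72e-05), as were Akap5 (1.02, adjusted p = 0.00267), the nuclear receptor Rorb (0.94, adjusted p = 0.000119) and the adenylyl cyclase Adcy9 (0.59). The kinase Camk2a was lower (-0.91, adjusted p = 0.000391), as were Ddc, which makes dopamine and serotonin (-0.39, adjusted p = 0.00113), the choline transporter Slc5a7 (-0.36) and the peroxiredoxin Prdx5 (-0.27, adjusted p = 0.00037). Oligodendrocyte markers were lower as a list (adjusted p = 1.58e-07; adjusted p = 0.271 with an estimated correlation). Of 13, 5 were called, among them Mbp (-0.28, adjusted p = 0.00463), Mobp (-0.30), Opalin (-0.50) and Ermn (-0.41), and 12 adjusted over the list alone. Markers of pericytes, smooth muscle and meninges were higher (adjusted p = 0.000597; adjusted p = 0.271 with an estimated correlation). Of 15, 4 were called, also adjusted over the list alone, such as Tagln (0.68), Myh11 (0.49) and Col1a2 (0.43). Endothelial markers were lower (adjusted p = 0.0162; adjusted p = 0.294 with an estimated correlation). Of 11, Vwf (-0.30), Slco1a4 (-0.24) and Cldn5 (-0.21) were lower and Abcb1a (0.36) was higher, and 1 higher and 6 lower adjusted over the list alone. Blood cell markers were lower (adjusted p = 0.0162; adjusted p = 0.271 with an estimated correlation; Hba-a3 -0.28, with 2 of 5 lower adjusted over the list alone). Interferon response genes were higher (adjusted p = 0.0101; adjusted p = 0.361 with an estimated correlation), with Ifi27 and Irgm (0.43, adjusted p = 0.000978) called of 25, also adjusted over the list alone. In total 1428 probe sets (4.6%) were called, 658 higher and 770 lower, and 285 did not overlap (chance 0.0011%). No array of this pair departed from its label.

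In AA rats against ANA rats, Hnmt, which degrades histamine, was 2.96-fold lower (-1.57 ± 0.134, adjusted p = 4.74e-07), and the zinc finger genes Zfp40 (-1.42 ± 0.11, adjusted p = 1.37e-07) and Zfp61 (-0.91, 3 of 3 probe sets) were lower. Dcaf6 (-0.69), the thioesterase-like Lyplal1 (-0.61), and the histone demethylase Kdm5b (-0.52) were also lower in AA. Smaller differences were those of Tti1 (-0.41), L3hypdh (-0.41), Aurkaip1 (-0.27) and Clic5 (-0.19). The mitochondrial RNA methyltransferase Nsun4 was 1.76-fold higher (0.81 ± 0.076, adjusted p = 1.97e-06). Tifab (1.71-fold), P3h4 (1.69-fold), the phosphatase regulator Phactr3 (1.67-fold) and Phf20 (1.62-fold) were higher, with the growth factor Tgfb2 (1.54-fold), Apba2 (1.48-fold), the histone deacetylase Hdac4 (1.46-fold, adjusted p = 8.28e-05), and Zfp956 (1.45-fold). The GMP synthase Gmps (0.39 log2) was higher as well. The arrays labelled AA and ANA did not overlap for any of these genes, AA 19 and ANA 20 included. These 2 arrays correlated most with sP (mean r 0.9949, own line 0.9795) and sNP arrays (0.9959, own line 0.9864). So the rule with all arrays also asked these 2 to lie on the side of their label, and it is not a clean separation of AA from ANA animals. The sign given held for 1 of 2 probe sets of Hnmt, Nsun4, Apba2 and L3hypdh, and for 4 of 5 of Dcaf6 and P3h4. Without the arrays labelled AA 19 and ANA 20, 9 animals against 9, Plekhh1 (7.87-fold), albumin (Alb, 6.9-fold, both probe sets), Pop5 (5.65-fold), Ccdc77 (5-fold, both probe sets), Chmp1b (4.9-fold), Fam107a (3.69-fold) and the sterol desaturase Sc5d (3.51-fold) were higher in AA. Fcrl2 (-2.20), Wdr37 (-1.76) and the kynurenine aminotransferase Aadat (-1.55) were lower. Here the sign held for 1 of 2 probe sets of Plekhh1, Pop5 and Wdr37, 2 of 3 of Sc5d and 3 of 4 of Chmp1b.

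Of the fixed lists in AA/ANA, the transcription factor Creb1 was lower (-0.79, adjusted p = 0.000166), as were Gsta4 (-0.66) and the quinone reductase Nqo1 (-0.21, adjusted p = 0.00547). Of 38 glutathione and antioxidant enzymes these 2 were lower and Gstm4 (0.29) was higher, with 1 higher and 4 lower adjusted over the list alone. The list itself had an adjusted p of 0.0932, and of 0.0292 without the departing arrays. The AMPA receptor subunit Gria4 (0.47, adjusted p = 0.00345), the astrocyte filament gene Gfap (0.92, adjusted p = 0.00289), and the class II antigen presentation genes Cd74 (1.06, adjusted p = 0.00661) and RT1-Da (0.92, adjusted p = 0.021) were higher. Oligodendrocyte markers were lower as a list (adjusted p = 0.000785; adjusted p = 0.976 with an estimated correlation; 0 of 13 called and 3 adjusted over the list alone). Oxidative phosphorylation (adjusted p = 0.0153; adjusted p = 0.956 with an estimated correlation; 0 of 64 called) and circadian clock genes (adjusted p = 0.0265; adjusted p = 0.784 with an estimated correlation; 0 of 16 called) were called higher as lists. Neither had members called when adjusted over the list alone, and without the departing arrays oxidative phosphorylation had an adjusted p of 0.243. Mx2 (2.83-fold, adjusted p = 0.000856), Oas1b (1.09) and Irgm (0.31) were called higher of the interferon response list, also adjusted over the list alone, whose own adjusted p was 0.201. In total 728 probe sets (2.35%) were called, 341 higher and 387 lower, and 48 did not overlap (chance 0.0011%). Without AA 19 and ANA 20 the count was 1378, with 718 of the 728 among them, and 375 did not overlap.

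On average the sP rats had lower expression of genes of medium spiny neurons, the main cell type of the striatum, than sNP rats. The sP arrays were unlike in the marker index, which contains these markers. It lay between 2.519 and 3.147 in sP 2, sP 5, sP 8 and sP 9. In the other sP arrays it lay between 4.021 and 4.807, against 4.026 to 5.529 in sNP. For the list of shared spiny neuron markers 9 of 100 splits of the animals gave as small a p. Of 11 markers shared by both kinds of spiny neuron 10 were lower, and 11 adjusted over the list alone (camera adjusted p = 3.8e-06; adjusted p = 0.42 with an estimated correlation). Among them were the phosphatase Ptpn5 (-0.62), Bcl11b (-0.60), Meis2 (-0.49) and the adenylyl cyclase Adcy5 (-0.85). All 5 measured markers of D2 neurons were lower (adjusted p = 0.00225; adjusted p = 0.42 with an estimated correlation), with Adora2a at -1.30, the dopamine receptor Drd2 at -0.996 (adjusted p = 0.0351) and the enkephalin precursor Penk at -0.79; all 5 also passed adjusted over the list alone. Of 7 D1 markers, Drd1 (-0.94), Eya1 (-0.72) and Pdyn (-0.71) were lower (adjusted p = 0.0033; adjusted p = 0.42 with an estimated correlation; 6 adjusted over the list alone). With the marker index as covariate, which is itself built from markers of spiny neurons, none of these 3 lists stayed called (adjusted p = 0.97, 0.698 and 0.68, the D1 list with its direction turned). Drd1 (0.028), Pdyn (0.039) and Drd2 (-0.039) then had differences near 0. Of 21 dopamine signalling genes 11 were lower and 0 higher, also adjusted over the list alone (adjusted p = 0.000285; adjusted p = 0.398 with an estimated correlation), including the G protein subunit Gnal (-0.51); with the index as covariate this list had an adjusted p of 0.665.

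Other groups differed in sP rats too. Oligodendrocyte precursor markers were higher (adjusted p = 0.00225; adjusted p = 0.42 with an estimated correlation). They were Vcan (0.39), Sox10 (0.33), Cspg4 (0.31) and Pdgfra (0.22), 4 of 6, and 5 adjusted over the list alone. Endothelial markers were lower (adjusted p = 0.0033; adjusted p = 0.42 with an estimated correlation), with Vwf (-0.84) and Abcb1a (-0.44) among 4 of 11, also adjusted over the list alone. Markers of pericytes, smooth muscle and meninges were higher (adjusted p = 0.048; adjusted p = 0.483 with an estimated correlation), with Dcn (0.55) among 3 of 15, and 4 adjusted over the list alone; without sP 4 and sNP 4 the adjusted p was 0.0505. Blood cell markers were lower as a list with 0 of 5 called, also adjusted over the list alone (adjusted p = 0.0447; adjusted p = 0.42 with an estimated correlation). Astrocyte genes Agt (1.14) and Gjb6 (0.84) and the septal and pallidal marker Zic4 (0.92, adjusted p = 0.0168) were higher, with an adjusted p of 0.0852 for either list. Adjusted over the list alone 6 astrocyte and 5 septal and pallidal markers were higher and 1 of each lower. Voltage-gated calcium channel genes were lower as a list (adjusted p = 0.0353; adjusted p = 0.634 with an estimated correlation). Of 17, 1 was higher and 4 lower, such as Cacna2d3 (-0.64), Cacna1d (-0.59) and Cacnb4 (-0.52), with 1 higher and 9 lower adjusted over the list alone. Oxidative phosphorylation genes were higher (adjusted p = 0.000474; adjusted p = 0.652 with an estimated correlation), with Uqcrc1 (0.21) and Ndufa9 (0.16) among 3 of 64, and 0 adjusted over the list alone. With the index as covariate calcium channels (adjusted p = 0.956) and oxidative phosphorylation (0.174) turned direction and were not called.

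Receptors and peptides with a place in alcohol research differed one by one in sP/sNP, in lists that were not called. For comparison, 2153 of all 14217 genes were called in this pair on the probe set used for the lists. Of 7 metabotropic glutamate receptors, Grm2 (-0.59, adjusted p = 0.000132), Grm4 (-0.52), Grm7 (-0.47) and Grm3 (-0.29) were lower and 1 was higher (list adjusted p = 0.0596; 2 higher and 5 lower adjusted over the list alone). Of 12 GABA-A receptor subunits, Gabra4 (-1.14), Gabra2 (-0.68) and Gabra5 (-0.55) were among 4 lower and Gabre (0.65) among 2 higher (list adjusted p = 0.447; 3 higher and 4 lower adjusted over the list alone). Of 23 non-opioid neuropeptides Cartpt (-0.94) and Npy (-0.34) were lower and 1 was higher, also adjusted over the list alone (list adjusted p = 0.61). Of 25 neuropeptide receptors 4 were lower, among them the melanocortin receptor Mc4r (-0.92), and 4 higher (list adjusted p = 0.56; 8 higher and 6 lower adjusted over the list alone). Of 20 immediate early genes Arc (-0.72), Egr1 (-0.69) and Homer1 (-0.64) were among 4 lower and Jun (0.25) among 2 higher (list adjusted p = 0.19; 2 higher and 5 lower adjusted over the list alone). The orexin receptor Hcrtr2 (0.99), parvalbumin (Pvalb, 1.07), the glial factor receptor Ret (0.79), catalase (Cat, 0.42) and Hdac4 (0.35) were higher. With the marker index as covariate Grm2 (-0.68) and Hdac4 (0.37) stayed called, the other receptors, peptides and early genes named did not, and Cartpt (0.016), Egr1 (0.024) and Homer1 (0.05) turned to differences near 0 with the other sign.

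The naming rule takes the largest differences among genes that did not overlap between 9 sP and 9 sNP animals, and it gave other genes, apart from Vwf. Fam111a, a protease that restricts viruses, was 16.2-fold higher in sP (4.01 ± 0.396, adjusted p = 4.31e-06) and 22.7-fold without the arrays labelled sP 4 and sNP 4. The inhibitory IgG receptor Fcgr2b (2.37-fold) and the neuronal kinesin Kif5c (1.08 log2) were higher, as were the G protein regulator Rgs17 (1.87-fold), the nuclear receptor Nr2c1 (1.85-fold), Rexo4 (1.83-fold) and Phactr3 (1.8-fold). Mpeg1, a pore-forming protein of macrophages, was 6.35-fold lower (-2.67 ± 0.265, adjusted p = 4.31e-06), and Tnfaip6, which binds hyaluronan, 5.1-fold lower (-2.35 ± 0.215, adjusted p = 2.85e-06; both probe sets). Eeig2 (3.17-fold), the adhesion receptor Adgrg6 (2.76-fold), Jhy (2.63-fold), the calcineurin subunit Ppp3r1 (1.8-fold) and Vwf (1.79-fold) were lower, as were Phip, Eml1 and Sgcb (-1.10, -1.07 and -1.08 log2). The sign held for 1 of 2 probe sets of Phactr3, 3 of 5 of Rgs17 and 1 of 3 of Sgcb. Of the 4 probe sets of Lysmd4, 3 were lower (-0.82, -0.77 and -0.96), and the fourth was higher (2.78, adjusted p = 2.85e-06), the same signs as in HAD2/LAD2.

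The marker index, the mean of spiny neuron markers minus that of pallidal and septal markers, was 3.68 ± 0.961 (SD, n = 9) in sP and 4.87 ± 0.563 (SD, n = 9) in sNP. The difference of -1.19 did not pass (exact permutation test, two-sided, p = 0.00671; adjusted p = 0.0671 over 10 tests, and 0.0793 without the departing arrays). The other 9 tests of the index and of Gapdh had adjusted permutation p of at least 0.456. The Gapdh 3' minus 5' value differed by at most 0.188 between the lines of a pair but was 4.71 and 4.90 in HAD1 and LAD1 and 2.91 and 2.83 in HAD2 and LAD2, against 0.403 and 0.468 in sP and sNP. Without the departing arrays, across 31008 probe sets, which are not independent replicates, the sP minus sNP difference correlated with the slope of each probe set on the index within the lines of the other 4 pairs (73 arrays; r = -0.76, rho = -0.729). In the other pairs the same r was 0.0592 (P/NP), -0.136 (HAD1/LAD1), 0.196 (HAD2/LAD2) and 0.116 (AA/ANA).

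**Figure D2:**
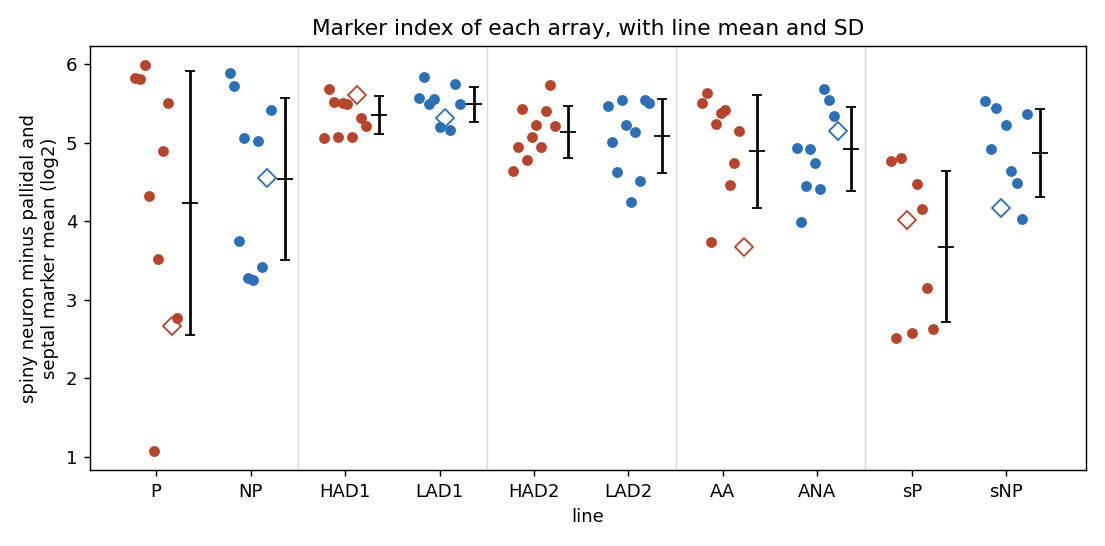
Marker index of each array (vertical axis, log2; spiny neuron markers minus pallidal and septal markers) by line, with the line mean and SD; open diamonds are the 8 departing arrays. The mean is 3.68 in sP and 4.87 in sNP, and P and NP arrays spread most widely (SD 1.68 and 1.03).

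**Figure D3:**
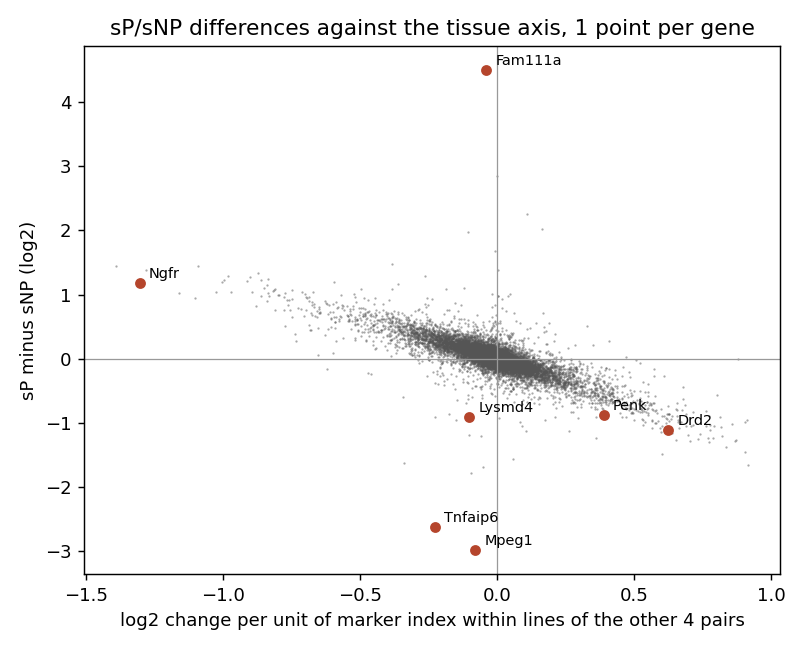
Each point is 1 gene: the horizontal axis is its slope on the marker index within the lines of the other 4 pairs (log2 per unit of the index) and the vertical axis its sP minus sNP difference (log2), both without the departing arrays. By gene r was -0.797; Drd2 (slope 0.63, difference -1.12) lies along the trend, whereas Fam111a (slope -0.04, difference 4.50) and Mpeg1 (slope -0.08, difference -2.98) lie apart from it.

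In total 4006 probe sets (12.9%) were called in sP/sNP, 2197 higher and 1809 lower (1807 and 2005 with array medians subtracted), with a median size of 0.349 log2, and 152 did not overlap (chance 0.0041%). Without sP 4 and sNP 4 the count was 4657, and 419 did not overlap; 203 calls were over 2-fold, against 130 with all arrays. With the marker index as covariate, an alternative chosen after the data were seen, 317 were called, and with the Gapdh value as covariate 863. Of the 130 calls over 2-fold 59 stayed called the same way with the index as covariate (45.4%), against 226 of 3876 smaller ones (5.83%). Leaving out 1 array at a time moved the count by more than 1.5 times for sNP 1 (1272), sP 2 (1032), sNP 3 (1031), sP 5 (1098), sNP 5 (1319), sNP 6 (2379), sP 8 (1142), sP 9 (1139) and sNP 9 (1221). Of these, sP 2, sP 5, sP 8 and sP 9 had the lowest marker index of the sP arrays (2.519, 2.577, 3.147 and 2.635). The highest of the sNP arrays were those of sNP 1, sNP 3, sNP 5 and sNP 9 (5.529, 5.441, 5.223 and 5.368). Leaving out sP 1 (index 4.769), sP 3 (4.807) or sNP 8 (4.026) raised the count to 5634, 5821 and 5095. The count thus largely followed the marker index of the array left out, but not for sNP 2 (4.915, 3921 calls).

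**Figure D4:**
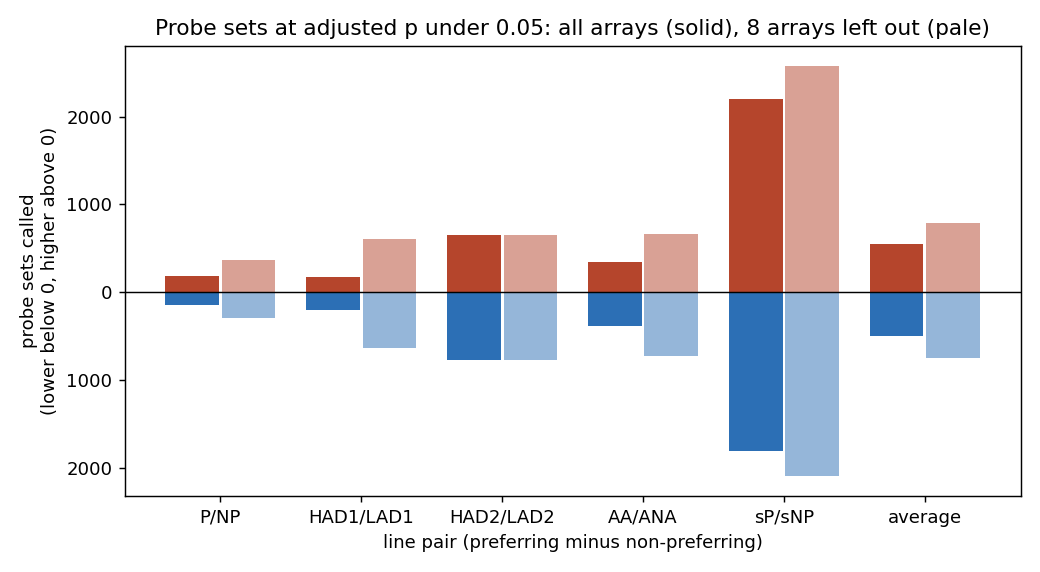
Number of probe sets called per line pair and on average over the 5 pairs (vertical axis; higher in the preferring line above 0, lower below), with all arrays (solid) and without the 8 departing arrays (pale). The counts with all arrays run from 326 in P/NP to 4006 in sP/sNP.

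Few genes differed the same way in several line pairs. The zinc finger gene Zfp212 was called higher in 4 of the 5 preferring lines (P 0.45, HAD2 0.54, AA 0.47, sP 0.56; HAD1 1.1 with an adjusted p of 0.0515) on a dim probe set (mean log2 5.68). Its brighter probe set (mean log2 10.1) went the other way, with -0.35 in HAD1, -0.17 in AA and -0.14 in sP called lower. Gsta4 was called lower in 4 preferring lines (HAD1 -0.86, HAD2 -0.55, AA -0.66 and sP -0.36) and higher in P (0.75), with an interaction adjusted p of 3.57e-09. RT1-T24-4 was called higher in HAD2 (2.33) and sP (0.50), and in 4 pairs without the departing arrays. Tmem14a was called lower in 3 preferring lines and in 4 without the departing arrays.

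Of 5949 probe sets called in any pair, 5192 were called in 1 pair alone. Of the 757 called in 2 or more pairs, 462 (61%) were called higher in 1 preferring line and lower in another, such as Mx2 and Akap5 in HAD1/LAD1 and HAD2/LAD2. Called the same way in at least 3 pairs were 31 probe sets (13 higher and 18 lower; 14 named genes), where independent lists would share 2.95; but turning the direction of whole pairs gave 31 to 48 (median 42), so the real directions agree no more than others. There were 3 in at least 4 pairs (0.0167 for independent lists). Without the departing arrays these counts were 79 (10.9 for independent lists, 88 to 123 for other directions) and 6 (0.121). HAD1/LAD1 and HAD2/LAD2 shared 129 calls, 62 the same way and 67 opposite, against 8.59 and 8.48 for independent lists. HAD2/LAD2 and sP/sNP shared 300, of which 192 were opposite (92.8 for independent lists). AA/ANA and sP/sNP shared 141 calls, 93 the same way, but without the departing arrays 297, of which 125 went the same way. On the marker genes of sP/sNP (0 at sNP, 1 at sP) the arrays labelled AA 19 and ANA 20 lie at 0.999 and -0.0136. With all arrays they therefore pull the AA minus ANA difference towards that of sP minus sNP. Agreement of these 2 comparisons with all arrays is thus not independent. Across probe sets the differences of any pair of comparisons correlated with r between -0.139 (HAD2/LAD2 with sP/sNP; rho -0.248) and 0.093 (P/NP with sP/sNP; rho 0.129). None of these 10 passed (permutation p from 0.36 to 0.98, adjusted p at least 0.967; the smallest p that 100 permutations can give is 0.01). Without the departing arrays the r of P/NP with sP/sNP was -0.0243 and that of AA/ANA with sP/sNP -0.1, from 0.0498 with all arrays. In a limma F test 3626 probe sets had a difference that depended on the line pair (5420 without the departing arrays), among them 74 of the 78 probe sets named in the pairs. Those 78 were picked for large differences within single pairs of these same data. Their share is therefore no separate evidence of dependence on the pair.

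Averaged over the 5 pairs, Paqr8, the membrane progestin receptor, was lower in preferring lines (-0.87 ± 0.09, adjusted p = 1.15e-11, with a negative sign in 5 of 5 pairs and called in 3). Also lower with the same sign in all pairs were the intramembrane protease Sppl2a (-0.65), Slc52a2 (-0.58), Aadat (-0.50), Rock2 (-0.46), the synaptic kinase Camk2a (-0.42, adjusted p = 0.00187; 4 of 4 probe sets negative) and the lipid transfer protein Stard10 (-0.39). Several of these differences were unequal between pairs, with an interaction called. The largest and smallest were -1.85 (HAD2) and -0.06 (sP) for Sppl2a and -1.69 (HAD2) and -0.02 (AA) for Slc52a2. They were -1.44 (AA) and -0.03 (HAD1) for Aadat, -1.19 (HAD2) and -0.04 (AA) for Rock2, and -1.30 (HAD2) and -0.03 (P) for Stard10. The sialyltransferase St6galnac5 (-0.37), Ap5m1 (-0.36), the nucleoside kinase Dck (-0.33), Gas7 (-0.32) and Greb1 (-0.31) were lower in the same manner. Higher with the same sign in all pairs were Zfp212 (0.62 ± 0.072, adjusted p = 4.62e-10, with its other probe set at -0.16), Creg2 (0.50, with 2.00 in sP/sNP and an interaction adjusted p of 1.35e-10) and the interneuron transcription factor Dlx1 (0.37, adjusted p = 0.0133). So were the matrix protein Tnc (0.34), Rorb (0.34, adjusted p = 0.000107) and the collagens Col24a1 (0.33) and Col12a1 (0.29). The transcriptional cofactor Zfpm2 (0.31 ± 0.074, adjusted p = 0.00527), the G protein regulator Rgs18 (0.29), Tgfb2 (0.29), Apba2 (0.27) and Oxr1 (0.26) completed this group. Tmem14a (-0.27 ± 0.037, adjusted p = 1.11e-07) was lower as well. The 5 differences of Zfpm2 (interaction adjusted p = 0.997), Dlx1 (0.849), Oxr1 (0.834) and Tnc (0.825) were not called unequal. By contrast, 12 of the 24 named genes had an interaction, Paqr8, Rorb, Tgfb2, Col12a1, Apba2 and Ap5m1 among them. The sign given held for 1 of 2 probe sets of Slc52a2 and Apba2, 2 of 3 of Dck and Zfpm2, and 3 of 4 of Paqr8, Sppl2a and Rock2.

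**Figure D5:**
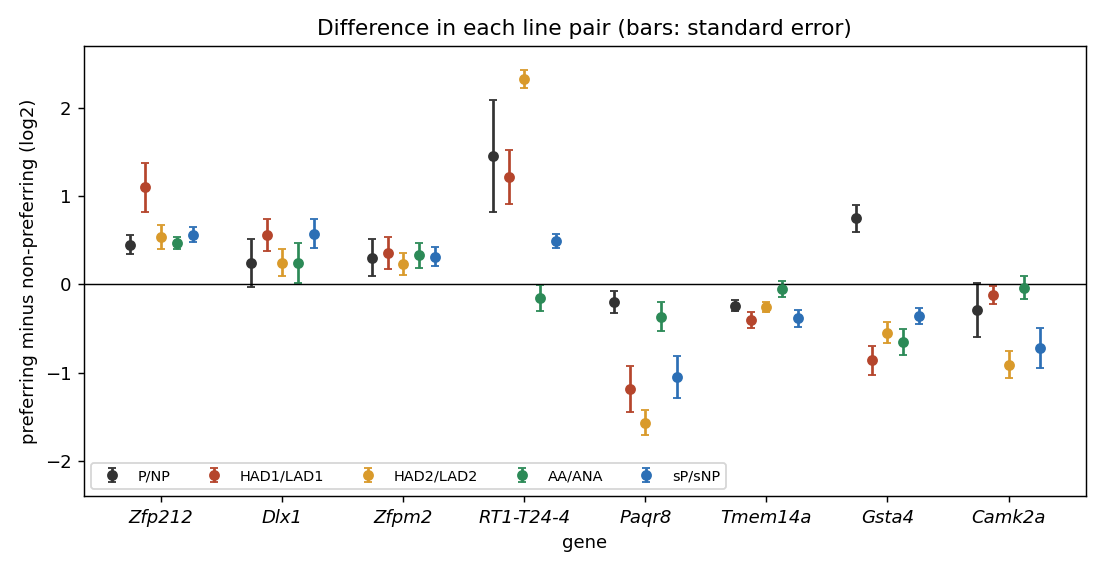
Difference between the preferring and the non-preferring line (vertical axis, log2, with its standard error) in each of the 5 line pairs for 8 genes, all arrays. The Zfp212 probe set drawn lies above 0 in all 5 pairs and Paqr8 below 0 in all 5, while Gsta4 is at 0.75 in P/NP and at -0.86, -0.55, -0.66 and -0.36 in the other pairs.

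Of the fixed lists, interferon response genes were higher on average in preferring lines (adjusted p = 9.16e-08; adjusted p = 0.173 with an estimated correlation). Of 25, Oas1b (0.53, adjusted p = 5.54e-05), Ifi27 (0.39), Mx2 (0.28) and Irgm (0.21) were called, and 10 adjusted over the list alone. Mx2 went both ways between pairs. Without the departing arrays its 2 probe sets were called lower in HAD1/LAD1 and higher in AA/ANA, and 1 of them was called higher in HAD2/LAD2. Ifi27 was called higher in 2 pairs and its differences were unequal (interaction adjusted p = 1.5e-07). Candidate genes of alcohol preference from earlier rat work were lower (adjusted p = 0.042; adjusted p = 0.173 with an estimated correlation). Of 19, Gsta4, Creb1 (-0.23, adjusted p = 0.00135) and the aldehyde dehydrogenase Aldh2 (-0.17, adjusted p = 0.03) were called, also adjusted over the list alone. Heat shock proteins and chaperones were higher (adjusted p = 0.042; adjusted p = 0.784 with an estimated correlation; Bag3 0.24 and Pdia4 0.15 of 26, also adjusted over the list alone). Oxidative phosphorylation genes were called higher as a list (adjusted p = 0.042; adjusted p = 0.978 with an estimated correlation), although Ndufa12 was lower (-0.09) and Cox6c higher (0.06) among 64, also adjusted over the list alone. With the marker index as covariate the alcohol preference candidates from earlier rat work list, average (adjusted p = 0.147), the heat shock proteins and chaperones list, average (0.364) and the oxidative phosphorylation list, average (0.772) were not called. Microglial markers were lower (adjusted p = 0.000337; adjusted p = 0.392 with an estimated correlation), with Cx3cr1 (-0.17, adjusted p = 8.99e-07), C1qa (-0.20) and Ctss (-0.14) called of 12 and 5 adjusted over the list alone.

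Other cell type lists on average had few called members. Oligodendrocyte markers (adjusted p = 0.000962, and 0.392 with an estimated correlation; Mal -0.23, 1 of 13) and endothelial markers (adjusted p = 0.0337, and 0.392; Vwf -0.23 and Slco1a4 -0.12 of 11) were lower, both also adjusted over the list alone. Markers of pericytes, smooth muscle and meninges were higher (adjusted p = 0.00124, and 0.392; Dcn 0.23, with 1 of 15 called and 4 adjusted over the list alone). Spiny neuron markers of both kinds (adjusted p = 0.00124), D1 (0.0261) and D2 (0.0296) were called lower as lists and cortical glutamatergic markers higher (0.0255), with 0 members called, also adjusted over the list alone, and an adjusted p = 0.392 with an estimated correlation for each. Without the departing arrays the D1, D2 and endothelial lists had an adjusted p of 0.0722 and were no longer called. With the marker index as covariate the medium spiny neuron, both kinds list, average (adjusted p = 0.393), the D1 medium spiny neuron list, average (0.842) and the D2 medium spiny neuron list, average (0.853) turned direction and were not called. Of the lists that were not called, the metabotropic glutamate receptor Grm5 was lower (-0.83, adjusted p = 3.01e-08) and Hdac4 (0.22, adjusted p = 8.99e-07), Nrg1 (0.40), Adcy9 (0.32) and the potassium channel gene Kcna2 (0.21) were higher on average. Such averages need not hold in each pair. The Grm5 probe set named in HAD2/LAD2 (-2.57 there) was called in 2 pairs, with an interaction adjusted p of 4.24e-10 in the limma F test. Hdac4 was called in 2 pairs (interaction adjusted p = 2.66e-05). The Nrg1 probe set named in HAD1/LAD1 was called in 1 pair (0.0019). Interactions of Adcy9 and Kcna2 are not given here.

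With an estimated correlation none of the list calls held in any comparison.

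In total 1046 probe sets (3.37%) were called on average, 552 higher and 494 lower, with a median size of 0.173 log2; 280 of them had the same sign in all 5 pairs, and 669 also had an interaction. Without the departing arrays the count was 1535. This average uses the spread between animals of these 10 lines. With the line pair as the replicate, limma called 0 probe sets (1214 at an unadjusted p under 0.05), and the adjusted p of the named genes was 0.948, or 0.778 for Zfpm2. Over all probe sets, 1957 (6.3%) had the same sign in all 5 pairs, against 6.25% if signs were independent.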

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

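The tests of the 8 departing arrays, the correlation with slopes on the marker index, the fit with the index as covariate and the sizes under it, the test of the Gapdh slopes, the adjustment of the list splits and the test on probe sets of the same gene were chosen after the result was seen; the splits of the animals and the other tests were planned.

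Each of the 8 departing arrays lay apart from the other animals of its line on the label score by Dixon's test, which by chance marks about 1 in 20 groups. The same score had defined these arrays, so for them the test adds no separate evidence. Over the label score, the marker index and the Gapdh value 10 of 30 groups were marked, those of the 8 arrays among them. The arrays labelled HAD1 28 (0.00493) and LAD1 37 (0.988) sit at the other end of their pair's axis, at -0.00127 and 1.04 on the median of its marker genes, so an exchange of these labels could account for them. For the arrays labelled AA 19 (-0.039) and ANA 20 (0.93) such an exchange is excluded, since their markers scatter over 1.53 and 1.46 times the distance between the lines, and both sit at the ends of the sP/sNP axis (0.999 and -0.0136), as RNA of sP and sNP rats would; the other 6 departing arrays scatter over at most 0.758. The arrays labelled P 9 (0.463, position 0.547), sP 4 (0.399, position 0.441) and sNP 4 (0.483, position 0.387) lie between the lines, the 3 that a mixture of RNA or a cross could give (sP 4 and sNP 4 are also the closest of all pairs of arrays, r = 0.99817, next 0.99805), whereas the other 3 on their own axis lie within 0.04 of an end, so that a mixture is excluded for them. NP 9 (1.05, position 0.998) lies at the P end without a partner at the NP end, which argues against an exchange with P 9, as the place of both arrays between the lines does for sP 4 and sNP 4; a single wrong label for NP 9 stays open, as does a biological difference between animals, which was not tested.

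The sP/sNP differences run along the contrast of spiny neuron against pallidal and septal genes. A different share of neighbouring tissue in the punches of the lines may account for part of it: the difference correlates across probe sets with the within-line slope on the marker index in the other pairs (r = -0.76), and of 130 calls over 2-fold 59 (45.4%) stayed with the index as covariate, as did 226 of the 3876 smaller ones (5.83%). The differences themselves shrank, in the median of the 3876 from 0.342 (SE 0.0896) to 0.0869 (SE 0.0721), with 228 signs turned, and in that of the 130 from 1.19 (SE 0.268) to 0.573 (SE 0.19), with 12 turned. Of RNA degradation the tests leave open what share it has: with the Gapdh covariate the count fell to 863, as predicted for that cause, but the slopes on the Gapdh value correlate with the difference at 0.0717, no more than in HAD2/LAD2 (0.0965). Of the 4006 calls 0 turned their sign with the Gapdh covariate, against 240 with the index, and sizes under it were not compared. The highest Gapdh value of this pair was that of sNP 1 (0.8), and leaving out sNP 1 alone gave 1272 calls. This fall does not single out the Gapdh value. Leaving out sP 9, with the lowest Gapdh value (0.312), gave 1139 calls, and leaving out sNP 3 (0.39) gave 1031. The marker index of sNP 1 was also the highest of the pair (5.529). A difference between the lines in the composition of the accumbens itself predicts the same correlation and was not tested.

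In HAD1/LAD1, HAD2/LAD2 and AA/ANA large differences often stood on 1 probe set of a gene that has several. A sequence variant under the probes or an alternative transcript end is a candidate explanation: without the departing arrays, 46.9%, 42.6% and 53.8% of the other bright probe sets of the same genes had the same sign for differences over 2-fold, against 62.3%, 66.4% and 69.2% for smaller ones. The pairs are unlike in this, so the pooled 57.8% against 77.6% does not describe each: P/NP had 71.4% of 14 against 69.2%, and sP/sNP 81.8% of 55 against 86.5%. Probe sequences and variants of these lines were not used here, so a real difference in some transcripts of the gene stays open.

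The Gapdh 3' minus 5' value of the array labelled AA 19 was 0.541 and that of sNP 1 was 0.8, each apart from the other animals of its line by Dixon's test. Over the named genes, 24 of 160 groups of animals (15%) had 1 animal apart from the others by the same test, 16 of them on departing arrays. By the limma F test 3626 probe sets had a difference that depended on the line pair, as did 74 of the probe sets named in the pairs and 12 of the genes named for the average. The 74 had been picked for large differences within single pairs, so they add no separate evidence. Called higher in 1 line pair and lower in another were 462 probe sets, which is weighed with the choices of direction under the second hypothesis on the lines.

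Among 100 splits of the animals within line pairs, the real one included, fewer than 5 gave a count as large for these results, the limit planned beforehand. These shares were taken 1 at a time and were not adjusted over the results. In P/NP 2 gave a count as large as 326 (highest other 5310), in HAD1/LAD1 1 as large as 371 (2), in HAD2/LAD2 1 as large as 1428 (1), in AA/ANA 2 as large as 728 (5000), in sP/sNP 2 as large as 4006 (6920), on average 1 as large as 1046 (11), and for the interaction 2 as large as 3626 (8180). In P/NP, AA/ANA and sP/sNP and for the interaction 1 other split gave more calls than the real one, several times as many in P/NP and AA/ANA. This points to a structure of the samples, and what it follows was not tested. A share of 2 in 100 does not exclude chance for these results. For calls shared the same way by at least 3 pairs 1 split was as large as 31 (highest other 0), but such splits take away the calls within each pair, so they do not bear on agreement between pairs. There all 16 choices of direction gave at least 31, and chance agreement in direction is not excluded. Of the lists, taken 1 at a time, fewer than 5 splits gave as small a p for the interferon response list on average (2; 8.53 as -log10 p, highest other 9.09), the microglia list in P/NP (2; 11.01, highest other 14.7) and the dopamine signalling list in sP/sNP (4; 5.04, highest other 6.53). So it was for interferon response (2) and microglia (1) in HAD1/LAD1, blood cells (4) in HAD2/LAD2, oligodendrocyte precursors (1) in sP/sNP, and chaperones (4), the candidates of alcohol preference (3) and microglia (2) on average. Adjusted over the 39 list calls no share of splits was under 0.05 (lowest 0.13), so chance is not excluded for a list picked from these. It could not be excluded for the number of called pathway lists (68 splits as large as 13, highest other 39), the oligodendrocyte list in HAD2/LAD2 (7; 8.004, highest other 11.3) and the spiny neuron list in sP/sNP (9; 6.62, highest other 9.02). Of the 39 list calls, pathways and cell types together, 29 were reached by 5 or more splits, and for none of these could it be excluded. They include oxidative phosphorylation in HAD1/LAD1 (32), AA/ANA (28), sP/sNP (37) and on average (42), the proteasome (18), cholinergic (13), endothelial (6) and blood cell (11) lists in P/NP and the cholinergic list in HAD1/LAD1 (5). In HAD2/LAD2 they are interferon response (13), endothelial cells (12) and pericytes (6) besides oligodendrocytes, and in AA/ANA the clock (12) and oligodendrocytes (25). In sP/sNP they are calcium channels (15), D1 (14) and D2 (9) markers, endothelial cells (12), pericytes (41) and blood cells (32). On average they are D1 (26), D2 (27) and shared spiny neuron markers (25), cortical neurons (17), oligodendrocytes (17), endothelial cells (14) and pericytes (15). With the line pair as replicate, all 16 choices of direction gave at least the real count of 0 (highest other 0), and 16 are too few for a share under 0.05.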

How the results depend on the processing

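The settings that left out the departing arrays, left out 1 array at a time or used the marker index were chosen after the data were seen. Leaving out dim probe sets, subtracting array medians, quantile normalization and trended robust eBayes kept each count of called probe sets within 1.5 times its value. No named gene turned its sign under the scalings: 395 kept and 18 lost their call with array medians subtracted, and 400 kept and 13 lost it with quantile normalization. Other settings cost more of these calls. With the Gapdh covariate 115 were lost, with 1 fit over all lines 61 and with a minimum fold of 1.1 250. With the marker index 136 were lost and 8 called differences turned their sign. With array medians subtracted sP/sNP had 1807 higher and 2005 lower calls, against 2197 and 1809, so which direction holds more calls depends on the scaling. With quantile normalization 9 higher and 21 lower probe sets were called the same way in at least 3 pairs, against 13 and 18. With the line pair as replicate limma called 0 probe sets under every setting run (1214 at an unadjusted p under 0.05 with all arrays). The precision is limited by the number of arrays and, for dim probe sets, by a signal near background.

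Where settings moved a count by more than 1.5 times, the cause was not tested unless stated. For P/NP (326) the count was 759 with 1 fit over all lines, 562 with array weights, 180 with the Gapdh covariate, 661 without the departing arrays, 923 with the marker index and 1554 with both. For HAD1/LAD1 (371) it was 743 with 1 fit over all lines, 842 with array weights, 1237 without the departing arrays, 145 with the index and 926 with both. For AA/ANA (728) it was 1637 with array weights, 1378 without the departing arrays and 1821 with the index as well. For sP/sNP (4006) it was 863 with the Gapdh covariate, 317 with the index, and 423 with the index and without the departing arrays. On average over the pairs (1046) it was 1622 with array weights and 2084 with the index and without the departing arrays, and the interaction (3626) was 8524 with array weights. At least 3 pairs shared 31 probe sets the same way, but 54 with 1 fit over all lines, 84 with array weights, 79 without the departing arrays and 95 with the index as well. Without the departing arrays the correlation of the differences moved by more than 0.1 for P/NP with sP/sNP (-0.0243, from 0.093) and AA/ANA with sP/sNP (-0.1, from 0.0498).

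A minimum fold of 1.1 asks for larger differences by construction. It left 75, 56, 534, 267 and 273 calls in P/NP, HAD1/LAD1, HAD2/LAD2, AA/ANA and sP/sNP, 80 on average and 3 in at least 3 pairs, and it cannot be applied to an F test. With 1 probe set per gene fewer probe sets were tested, and the counts were 129, 109, 645, 238, 2629, 431 on average, 1710 for the interaction and 9 (2 higher, 7 lower) in at least 3 pairs. Called pathway lists were 13 over all comparisons, 0 with the estimated correlation and 22 with the mean of a gene's probe sets. Of the 39 list calls, pathways and cell types together, 6 were lost with the dimmest 40% of probe sets left out. With the mean of a gene's probe sets 2 were lost, and without the departing arrays 9.

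Leaving out 1 array at a time gave 240 to 552 calls in P/NP (552 without NP 9), 1273 to 1564 in HAD2/LAD2 and 577 to 1080 in AA/ANA. In HAD1/LAD1 it gave 178 to 795, with more than 1.5 times less or more for HAD1 21 (216), HAD1 22 (231), HAD1 23 (246), HAD1 24 (228), HAD1 26 (239), HAD1 28 (754), HAD1 29 (231), LAD1 31 (243), LAD1 32 (178), LAD1 33 (224), LAD1 34 (187), LAD1 35 (208), LAD1 37 (795), LAD1 38 (226) and LAD1 40 (239). In sP/sNP it gave 1031 to 5821, with such moves for sNP 1 (1272), sP 2 (1032), sNP 3 (1031), sP 5 (1098), sNP 5 (1319), sNP 6 (2379), sP 8 (1142), sP 9 (1139) and sNP 9 (1221). There the count largely followed the marker index of the array left out, as given with the results of sP/sNP. Leaving out 1 line pair gave 857 to 1346 on average over the pairs, and 2157 to 5015 for the interaction, with more than 1.5 times less without HAD2/LAD2 (2157) and without sP/sNP (2264).

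With the animal number as a replicate block, P/NP had 197 calls and sP/sNP 5035. Not every number pairs its animals, so the block was not used elsewhere: the correlation between animals of the same number ran from -0.591 to 0.774 in P/NP, with 6 of 10 above 0.1 and 8 of 20 arrays closest to their own number, and from -0.22 to 0.56 in sP/sNP, with 5 of 9 and 3 of 18. In a test added after the data were seen, shuffled numbers gave 1.99 such arrays on average in P/NP, with at least 8 in 11 of 10000 shuffles, and at least 3 in 3359 of 10000 in sP/sNP. In P/NP this is a hint from the data, not from the design, that some numbers are shared for a reason the labels do not give.

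Adding the index, which contains spiny neuron markers, turned the direction of some lists, none of them called then: in sP/sNP calcium channels (adjusted p = 0.956), oxidative phosphorylation (0.174) and D1 markers (0.68), and, for the average over the pairs, D1 medium spiny neuron list, average (0.842), D2 medium spiny neuron list, average (0.853) and medium spiny neuron, both kinds list, average (0.393). Some genes lower in sP turned to differences near 0, all with an adjusted p of at least 0.998: with the index and, after it, also without the departing arrays, Pdyn 0.039 and 0.052, Cartpt 0.016 and 0.009, Prkcb 0.025 and 0.01, Egr1 0.024 and 0.024, Homer1 0.05 and 0.049, Rarb 0.004 and 0.011, Drd1 0.028 and 0.044, Lamp5 0.041 and 0.052, and Grm4 0.004 with both.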

Other observations

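The hypothesis on neighbouring genes and that on directions were tested as planned; the calls without the departing arrays, on which the first rests, were chosen after the data were seen.

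Genes of the major histocompatibility complex and antigen presentation differed in single members and both ways. In HAD2/LAD2 RT1-T24-4 (2.33) and RT1-S3 (0.99) were among 3 higher, and RT1-M3-1 (-0.46) and RT1-DMb (-0.45) among 4 lower of 22, with 5 higher and 4 lower adjusted over the list alone and an adjusted p of 0.535 for the list. In sP/sNP RT1-T24-4 (0.50) and RT1-DMa (0.19) were higher and RT1-CE16 (-0.39) and RT1-CE5 (-0.18) were among 3 lower (list adjusted p = 0.996; 3 higher and 3 lower adjusted over the list alone). On average RT1-T24-4 (1.07) and RT1-S3 (0.34) were among 3 higher, and RT1-Bb (-0.24) and RT1-CE5 (-0.15) were lower (list adjusted p = 0.974; 3 higher and 3 lower adjusted over the list alone).

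Clock and stress genes differed in the sP/sNP pair as single genes. For comparison, 2153 of all 14217 genes were called in this pair on the probe set used for the lists. With the marker index as covariate 317 probe sets were called, against 4006. Of 16 clock genes Npas2 (-0.70), Bmal1 (-0.41) and Tef (-0.33) were lower and Bhlhe40 (0.30) was higher in sP (list adjusted p = 0.104; 2 higher and 3 lower adjusted over the list alone). Of 26 heat shock proteins and chaperones Bag3 (0.60), Cryab (0.40) and Dnajb1 (0.23) were among 4 higher and Hsph1 (-0.25) was lower (list adjusted p = 0.11; 6 higher and 4 lower adjusted over the list alone). Of the histone deacetylases Hdac4 (0.35) and Hdac5 (0.16) were higher and Hdac2 (-0.25) was lower. Microglial genes in HAD2/LAD2 went both ways, with P2ry12 higher (0.69, adjusted p = 9.28e-06) and C1qa (-0.45) and Cx3cr1 (-0.24) lower, also adjusted over the list alone.

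Inbreeding or selection could fix stretches of chromosome in a line, so that called genes lie next to each other. Called genes with a called neighbour of another gene family were 86 in HAD1/LAD1, 109 in HAD2/LAD2, 97 in AA/ANA and 865 in sP/sNP, each above the highest of 1000 shuffles (58, 80, 64 and 862), and 24 in P/NP, within the shuffled range (highest 26). The planned rule asked the same of the numbers with neighbours of any family. There sP/sNP had 904, below the highest shuffle (912), so the rule was not met in sP/sNP, and P/NP had 28, above its highest (26). The other pairs had 94, 113 and 107, above 63, 84 and 70. For neighbours of another family the number in sP/sNP exceeds the shuffled mean only 1.12 times, against 2.1 to 2.67 times in the others. Such stretches could give these numbers in HAD1/LAD1, HAD2/LAD2 and AA/ANA, but neighbouring genes may also share their regulation. Called neighbours had the same direction in 59.1%, 46.7% and 48.1% of cases in these pairs, a share for which no shuffles were counted.

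A second hypothesis is that alleles were sorted between the lines without regard to preference. If so, turning the direction of line pairs gives as many probe sets called the same way in at least 3 pairs as the real directions do. All 16 choices of direction gave at least the real 31 (31 to 48 for the others, median 42), and without the departing arrays 79 against 88 to 123. So the prediction was met for the probe sets shared by at least 3 pairs. It would have failed only if the real count had exceeded that of every other choice. Meeting it therefore does not tell such sorting from other causes, such as a different share of tissue in the punches. Without the departing arrays the real count lay below all other choices, which the prediction did not address. The test has no bearing on probe sets called in 1 pair alone, nor on single genes.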
